A study of Mus musculus with 9 samples.

How the data were processed

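RNA of the mouse renal carcinoma line RENCA was sequenced in 9 libraries, 3 in each of 3 groups: empty vector, Ndufa4l2 knockout and rescue. Per the labels' protocols, total RNA was extracted with TRIzol and purified on columns, poly(A) RNA was selected on oligo-dT beads, and libraries were made from random-primed cDNA for Illumina sequencing, with directional and non-directional preparation both described, so the strand setting of the counts is not given in the sources used here. Knockout clones were obtained with a single guide in a Cas9 plasmid and screened by qPCR, and rescue cells were selected with puromycin at 1.5 ug/mL, per the labels' protocols. The labels name the molecule as genomic DNA although the protocol describes mRNA libraries. The series text speaks of fewer knockout libraries than the 3 that the labels and the table hold; all 3 were used.

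The submitters' processing notes name CASAVA, HISAT2, HISAT and TopHat2, with no versions or roles, and the genome build mm10. Counts per gene were deposited as whole numbers without normalization, per the file headers and the values; the read counter is not given in the sources used here. FPKM values were deposited per library, per the file headers, with a library size that was 0.906 to 1.08 times the count total, and were not tested. The authors' group means, their log2 fold changes and their p-values, raw and adjusted, stand in the same table per the file headers, and their test is not given in the sources used here. Gene coordinates are those of the deposited table.

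Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr on the groups (13326 of 54532), libraries were scaled by TMM factors, and a quasi-likelihood model with robust dispersion and 1 mean per group was fitted to all 9 libraries. Each comparison was an F-test with Benjamini-Hochberg adjustment over all genes tested, and an adjusted p under 0.05 was called. Standard errors are the log2 fold change divided by the square root of F. CPM values use the TMM-scaled library sizes. The 21 gene lists were fixed before the data were examined, as were the alternatives not named below as later additions. Lists were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data, with adjustment over the 21 lists of a comparison. With the estimated correlation, camera called 0 lists in each comparison at an adjusted p under 0.05, and 3, 4 and 2 lists at an unadjusted p under 0.05 in knockout against empty vector, rescue against knockout and rescue against empty vector. The lists covered respiratory-chain complexes, mitochondrially encoded mRNAs, the tricarboxylic acid cycle, glycolysis, hypoxia-inducible factor targets, fatty acid oxidation, antigen presentation, interferon-stimulated genes and chemokines. Others held NF-kappa-B response genes, NRF2 and antioxidant genes, ATF4 and p53 targets, and cell cycle and cholesterol synthesis genes. The rest were epithelial, mesenchymal and renal tubule genes, and markers of leukocytes and of endothelial cells and fibroblasts. A few genes stand in more than 1 list.

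Genes were named by a rule fixed in advance: Ndufa4l2 and Ndufa4; the 8 largest increases and 8 largest decreases of knockout against empty vector and of rescue against knockout, and 5 of each of rescue against empty vector, among called protein-coding genes other than predicted ones without a name, with a mean of at least 5 CPM in the higher group and no overlap between libraries; up to 4 members of each list with the smallest adjusted p, or up to 2 as values where fewer passed; and 6 genes per direction among those reversed or kept in rescue, ranked by the smaller of their absolute log2 changes in the comparisons that define the class, under the same filters in each. Some genes that the rule chose are not reported here. Genes that a list's count summarises were not all named, and some members are given for other comparisons than the one that chose them. Lists of lysosomal proteins and cytosolic chaperones were written after the data were seen.

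Replicates were compared before they were averaged, and all within-group pairs differed by more than sampling noise (chi-square per degree of freedom of 3.64 to 20.25). The test was checked on simulated counts for 13326 genes, of which 67 were changed 1.5-fold, 67 2-fold and 66 4-fold, as many up as down. In knockout against empty vector it recovered 67.2% of genes changed 1.5-fold, 74.6% at 2-fold and 95.5% at 4-fold, with 12 false calls among 170. In rescue against knockout the shares were 74.6%, 70.1% and 98.5% with 13 false calls among 175, and in rescue against empty vector 67.2%, 77.6% and 95.5% with 16 among 176. The share of false calls lay above the adjusted p threshold in every simulated comparison. Few genes were changed in the simulation, while 47.5% to 60.6% of the tested genes were called in the data. The simulation therefore does not check the scaling or the error rate where so many genes differ. Overlaps of comparisons that share a group were set beside 50 simulations of unchanged groups. GC content and the site of the guide came from the GENCODE M21 transcripts and annotation of GRCm38, the assembly also called mm10. Alternatives were RLE and upper-quartile factors, no low-count filter, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, the replicate number as a block, stricter thresholds, fry for the lists and leaving out each library. Alternatives chosen after seeing the data were leaving out the mitochondrial genome and scaling by library totals alone. Figures were drawn with matplotlib 3.10.9.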

Results

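Gene expression was measured by sequencing of poly(A)-selected RNA in RENCA cells, a mouse renal carcinoma line, in 3 forms. Empty-vector cells served as the reference. Knockout cells were grown from single-cell colonies after CRISPR editing of Ndufa4l2, which encodes a mitochondrial protein related to the respiratory-chain subunit Ndufa4. Rescue cells are described as knockout cells in which Ndufa4l2 was re-expressed from a lentivirus under puromycin selection. Each group had 3 libraries. Total counts were 22594195, 14685134 and 24172162 in empty-vector replicates 1 to 3, 17320025, 13106531 and 25305299 in knockout, and 26643877, 17429352 and 15164167 in rescue. Of 54532 genes in the table, 13326 had enough counts to be tested. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

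The groups were well separated. Log CPM values correlated across genes at a mean r of 0.992 within empty vector, 0.993 within knockout and 0.994 within rescue, against 0.978 between empty vector and rescue, 0.956 between empty vector and knockout and 0.956 between knockout and rescue (genes are not independent replicates). The first principal component held 59.5% of the variance and set knockout (52.5 to 57.8) apart from empty vector (-28.5 to -24.1) and rescue (-31.4 to -24.4). The second held 22.8% and parted empty vector (20.4 to 36.6) from rescue (-30.9 to -27.8). Genes of the mitochondrial genome took 7.01% ± 1.10 of the counts in knockout (SD, n = 3), 2.79% ± 0.55 in empty vector and 2.47% ± 0.21 in rescue. This share is also a sign of RNA quality.

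The targeted gene was near the detection limit in the unedited cells. Ndufa4l2 (chromosome 10, 127514967 to 127517154, plus strand, mm10) had 12, 6 and 16 counts in the empty-vector libraries, 7, 8 and 6 in knockout and 73, 48 and 35 in rescue, that is 0.520 ± 0.128, 0.453 ± 0.204 and 2.48 ± 0.239 CPM (SD, n = 3). It rose in rescue against knockout by 2.57 ± 0.34 log2 units (SE; edgeR adjusted p = 2.1e-06) and against empty vector by 2.20 ± 0.30 (edgeR adjusted p = 8e-06). Between knockout and empty vector the log2 change was -0.36 ± 0.42 (edgeR adjusted p = 0.47), so no difference was detectable at this depth; it ran from -0.68 without knockout replicate 2 to 0.01 without knockout replicate 3. The guide AGATGGCAGGAACTAGTCTA matches chromosome 10, 127514980 to 127514999, on the plus strand of the GRCm38 annotation, within exon 1 of Ndufa4l2, over the start codon at 127514982 to 127514984 and followed by GGG. A small edit at this site need not remove the mRNA, so these counts check the rescue label and not the knockout label. The 3' end of Ndufa4l2 overlaps Shmt2 on the other strand from 127517123 on, and whether counting used strand is not given in the sources used here, so a few of these counts may belong to Shmt2. The paralogue Ndufa4, a respiratory-chain subunit, stood at 106 ± 6.78 CPM in empty vector, 115 ± 4.53 in knockout and 102 ± 5.62 in rescue. Its change from knockout to rescue, -0.17 ± 0.06 (edgeR adjusted p = 0.027), did not pass in several alternatives, with an adjusted p of up to 0.89.

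**Figure D1:**
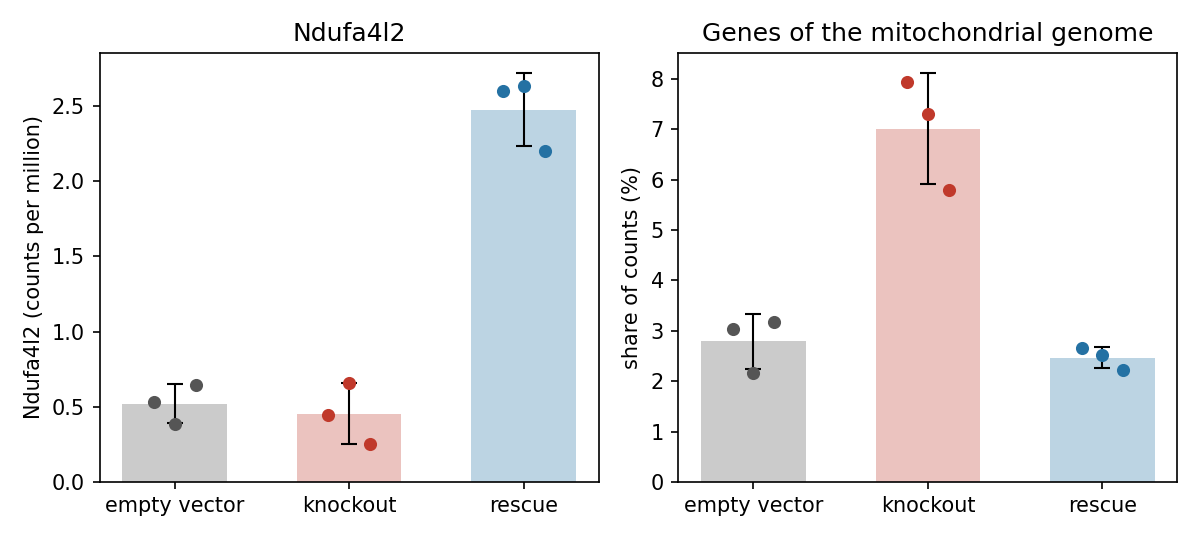
Ndufa4l2 in CPM (left) and the share of counts from genes of the mitochondrial genome in percent (right) for each library, with the group mean as a bar and the SD as an error bar (n = 3). Rescue averaged 2.48 CPM of Ndufa4l2 against 0.520 in empty vector and 0.453 in knockout, and the mitochondrial share was 5.79% to 7.93% in knockout and at most 3.17% elsewhere.

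Knockout against empty vector compared colonies edited at Ndufa4l2 with the reference cells. Whether the empty-vector cells were cloned is not given in the sources used here. Effects of losing the gene can therefore not be told apart from those of editing or clone choice. Of 21 gene lists, camera with a preset correlation called 7, all higher in knockout: interferon-stimulated, antigen-presentation, antioxidant, cholesterol synthesis and extracellular matrix genes, mitochondrially encoded mRNAs and leukocyte markers. With an estimated correlation camera called 0 of them, with a smallest adjusted p = 0.23 with an estimated correlation. The strongest single increases were in genes almost silent in empty vector. Vegfd, a lymphangiogenic growth factor, went from 0.709 ± 0.478 to 42.7 ± 4.07 CPM (SD, n = 3). Among genes that fell, Icam1, an adhesion molecule for leukocytes, dropped from 29.6 ± 1.00 to 2.83 ± 0.714 CPM, and Ppp1r15a, a phosphatase subunit of the stress response, from 534 ± 50.7 to 57.4 ± 2.61 CPM. In all, 3935 genes rose and 4143 fell at an edgeR adjusted p under 0.05, 60.6% of those tested, with a median size of 0.54 log2 units. At least a doubling or halving was seen in 1083 genes that rose and 523 that fell. The libraries of the groups did not overlap for 63.7% of genes, where chance gives 10%. With library totals alone as the scale, the median of all genes moved by -0.15 and the share of calls that were higher went from 48.7% to 34.4%.

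Other genes with the largest increases were Olfml3 (log2 change 5.75 ± 0.18, SE) and Bco1, which cleaves beta-carotene (5.65 ± 0.15). Afp, the fetal serum protein alpha-fetoprotein, stood at 0.0831 CPM in empty vector and 9.89 in knockout, and the integrin subunit Itga9 at 0.0362 and 5.73 CPM. Pla2g12a and Prrg1 had no count in the empty-vector libraries. Against a floor of 3 counts over that group they were at least 227-fold and at least 114-fold higher in knockout. The largest decreases, besides Icam1 and Ppp1r15a, were in Myo5b, a vesicle motor (-6.24 ± 0.28), Gpr161, a ciliary receptor (-5.60 ± 0.18), Il23a (-4.04 ± 0.23), Traf5 (-3.73 ± 0.26), Mum1l1 (-3.31 ± 0.23) and Il13ra1 (-3.18 ± 0.11). Over these increases and decreases, edgeR adjusted p-values ran from 5.8e-16 for Bco1 to 4.5e-06 for Ppp1r15a.

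Of 38 interferon-stimulated genes, 29 rose and 2 fell in knockout, also when adjusted over the list alone, with a median log2 change of 0.68. Rsad2, the antiviral protein viperin, rose from 47.2 ± 3.64 to 220 ± 31.8 CPM (SD, n = 3; edgeR adjusted p = 1.6e-11). Gbp7 rose by 2.02 ± 0.15 log2 units, Oasl1 by 1.32 ± 0.07 and Parp9 by 1.06 ± 0.06 (SE). Irf9 was among those that fell (-0.40 ± 0.07), and Cxcl10 did not pass (-0.18 ± 0.16). The list had a camera adjusted p of 1.3e-06, and an adjusted p = 0.47 with an estimated correlation. Of 17 genes of MHC class I antigen presentation, 13 rose and none fell, 14 when adjusted over the list alone. Tapbp, the peptide-loading protein tapasin, rose from 158 ± 18.2 to 699 ± 28.6 CPM. Pdia3 rose by 0.87 ± 0.09, Psmb8 by 0.77 ± 0.07 and Tap2 by 0.61 ± 0.06, while the heavy chain H2-D1 did not pass (-0.12 ± 0.07). For this list camera gave an adjusted p of 0.00011, and the adjusted p = 0.23 with an estimated correlation. Reads of the H2 and Oas families can be shared between near-identical copies, so these members are uncertain. Beside these lists stood 4 leukocyte marker genes with enough counts of 18, all of which rose, also adjusted over the list alone: the lysosomal protein Cd68 went from 76.3 ± 3.61 to 205 ± 9.58 CPM and Lyz2 from 0.949 ± 0.193 to 7.49 ± 1.00, with smaller rises of Csf1r (1.83 ± 0.25) and Cd79a (0.61 ± 0.19; without empty-vector replicate 3 its edgeR adjusted p was 0.08). The camera adjusted p was 0.0089, and the adjusted p = 0.23 with an estimated correlation. The general leukocyte markers Ptprc and Tyrobp had at most 2 counts in any library.

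In the list of NRF2 and antioxidant genes, 23 of 26 rose and none fell, also adjusted over the list alone. Hmox1 (-0.02), Gpx4 (-0.11) and Sod2 (0.01) did not pass. Gsta4 rose by 2.59 ± 0.13, Gstm1 by 1.67 ± 0.07, Gclm, which serves glutathione synthesis, by 1.64 ± 0.07 and Srxn1 by 1.46 ± 0.07. The median was 0.62 and the camera adjusted p 2.3e-08, with an adjusted p = 0.47 with an estimated correlation. Cholesterol synthesis genes rose in 20 of 21 cases, with a median of 0.97. Msmo1 rose by 0.98 ± 0.09, Hmgcs1 by 0.97 ± 0.06 and Srebf2, the regulator of the pathway, by 0.73 ± 0.08. In camera the adjusted p was 2.9e-08, and the adjusted p = 0.47 with an estimated correlation. Of 23 mesenchymal and extracellular matrix genes, 18 rose and 3 fell. The gelatinase Mmp2 rose from 7.76 ± 0.507 to 109 ± 2.26 CPM, Col6a1 by 4.48 ± 0.23 log2 units, Col6a2 by 3.72 ± 0.27 and Lox, a collagen crosslinker, by 2.96 ± 0.15, while Cyr61 fell by 1.13. The epithelial cadherin Cdh1 also rose, by 3.05 ± 0.14. The camera adjusted p for the mesenchymal list was 6.6e-05, and the adjusted p = 0.23 with an estimated correlation. The counts adjusted over the list alone were the same for the cholesterol and mesenchymal lists.

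Of 13 mitochondrially encoded mRNAs, 7 rose and none fell, also adjusted over the list alone. mt-Nd1 went from 1900 ± 422 to 7240 ± 1140 CPM and mt-Co1 from 11100 ± 2430 to 27600 ± 5600 (SD, n = 3), in step with the mitochondrial share of the libraries (7.01% against 2.79%). For this list the camera adjusted p was 0.0012, and the adjusted p = 0.50 with an estimated correlation. Several members, such as mt-Co2, share reads with near-identical nuclear copies and are uncertain. Nuclear respiratory-chain lists did not pass: 15 of 36 complex I subunits rose and 4 fell (median 0.18, camera adjusted p = 0.054), and 18 of 41 subunits of complexes II to V rose and 6 fell (median 0.12, camera adjusted p = 0.098). Ndufa8 rose by 0.56 ± 0.07 and Atp5o by 0.72 ± 0.06, while Uqcrc2 fell by 0.70.

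The remaining lists did not pass in camera for knockout against empty vector. In the tricarboxylic acid cycle list 4 of 23 genes rose and 10 fell, with Pcx, pyruvate carboxylase, up by 1.22 ± 0.08 and Dlat down (-0.56 ± 0.07). Glycolysis genes rose in 8 of 20 cases and fell in 4. Hypoxia-inducible factor targets rose in 11 and fell in 7 of 23, where the median was -0.09 and the mean 0.17; Lox was among the former and Adm, adrenomedullin, among the latter (-1.69 ± 0.08). Fatty acid oxidation genes rose in 7 and fell in 6 of 17 (median -0.07, mean 0.02). Chemokine and cytokine genes fell in 10 and rose in 3 of 20; Cxcl16 fell by 1.07 and Tgfb1 rose by 1.61 ± 0.09. NF-kappa-B response genes fell in 10 and rose in 3 of 20, with Tnfaip3, an inhibitor of that pathway, at -0.85 ± 0.10. ATF4 targets rose in 9 and fell in 10 of 26, p53 targets rose in 5 and fell in 6 of 17, and cell cycle genes rose in 11 and fell in 10 of 32, where cyclin D1, Ccnd1, fell by 1.81. Epithelial genes split 5 to 5 of 13 (median -0.03, mean 0.23), renal tubule genes 6 to 4 of 11, and the endothelial and fibroblast markers 1 to 1 of 3. Adjusted over the list alone, the counts differed from these by at most 1 gene.

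Rescue against knockout compared re-expressing cells with knockout cells. Effects of re-expression cannot be told apart here from those of the lentivirus, of puromycin or of a difference between clones. Whether the rescue cells descend from the sequenced knockout clone was not tested. With a preset correlation, camera called 8 of 21 lists: interferon-stimulated, antigen-presentation, matrix and cholesterol synthesis genes, mitochondrially encoded mRNAs and leukocyte markers were lower in rescue, and cell cycle and glycolysis genes higher. None of the 8 was called when the correlation was estimated, with a smallest adjusted p = 0.14 with an estimated correlation. Mmp2 fell from 109 ± 2.26 to 0.811 ± 0.0512 CPM (SD, n = 3), below its level in empty vector, and Rsad2 from 220 ± 31.8 to 10.6 ± 0.477 CPM. Gpr161, at 0.386 ± 0.168 CPM in knockout, rose by 5.15 ± 0.19 log2 units (SE), and Myo5b rose from 0.183 ± 0.191 to 6.04 ± 0.593 CPM. In all, 3928 genes rose and 3639 fell, 56.8% of those tested, and 276 and 1120 of them by at least 1 log2 unit. With library totals alone as the scale, the median of all genes moved by 0.18 and the share of calls that were higher went from 51.9% to 69.6%.

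Other genes with the largest increases were Islr2 (4.35 ± 0.23), Mum1l1 (4.27 ± 0.21), Gdf5, a growth factor of the BMP family (3.61 ± 0.18), Traf5 (0.632 to 8.71 CPM), the integrin subunit Itgb6 (3.30 ± 0.18) and Ddah1 (3.28 ± 0.18), with edgeR adjusted p-values from 2.8e-12 for Gdf5 to 1.4e-09 for Traf5. Largest decreases besides Mmp2 were in Zfp991 (9.88 to 0.0301 CPM), Apol6 (-7.19 ± 0.30), Adgrf5 (-6.98 ± 0.21), Itga9 (5.73 to 0.0301 CPM) and Pla2g12a (10.8 to 0.0119 CPM). Fhl1 and Prrg1 had no count in rescue and were at least 155-fold and at least 113-fold lower than in knockout, against a floor of 3 counts over the group. edgeR adjusted p-values of these decreases ran from 7e-20 for Mmp2 to 8.9e-10 for Prrg1.

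Of 38 interferon-stimulated genes, 35 fell and 1 rose in rescue against knockout, with a median log2 change of -2.13. Besides Rsad2, Irf7, a transcription factor of the interferon response, stood at -2.69 ± 0.08, Oasl1 at -2.43 ± 0.07 and Parp9 at -1.93 ± 0.07. In camera the adjusted p was 3.1e-18, and the adjusted p = 0.14 with an estimated correlation. Of 17 antigen-presentation genes 15 fell and none rose (median -0.89), among them Tapbp (-2.29 ± 0.08), the peptide transporter subunits Tap1 (-2.07 ± 0.07) and Tap2 (-1.38 ± 0.06), and Psmb8 (-1.59 ± 0.08). The camera adjusted p was 9.7e-08, and the adjusted p = 0.14 with an estimated correlation. All 4 tested leukocyte markers fell, with Cd68 at 35.9 ± 3.16 CPM in rescue and Lyz2 at 1.15 ± 0.275 (camera adjusted p = 0.0042; adjusted p = 0.14 with an estimated correlation). Mitochondrially encoded mRNAs fell in 9 of 13 cases and rose in none, with mt-Co1 at 6990 ± 401 CPM (camera adjusted p = 0.00034; adjusted p = 0.59 with an estimated correlation), as the mitochondrial share fell to 2.47%. Adjusted over the list alone, the counts of these lists did not change.

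Mesenchymal and matrix genes fell in 13 of 23 cases and rose in 4, or 14 and 4 adjusted over the list alone. Col6a1 (-5.40 ± 0.25) and Col5a1 (-1.38 ± 0.07) fell, while the matricellular gene Cyr61 rose from 337 ± 24.6 to 1020 ± 77.7 CPM (camera adjusted p = 0.0025; adjusted p = 0.14 with an estimated correlation). Cholesterol synthesis genes fell in 12 of 21 cases and rose in 2, with Msmo1 at -0.88 ± 0.09 and Srebf2 at -0.84 ± 0.08 (camera adjusted p = 0.0029; adjusted p = 0.78 with an estimated correlation). Cell cycle genes rose in 21 of 32 cases and 1 fell. Ccnd1 rose by 1.35 ± 0.08, Cdk1 by 0.76 ± 0.06, Bub1 by 0.68 ± 0.06 and Bub1b by 0.56 ± 0.06 (camera adjusted p = 0.00017; adjusted p = 0.59 with an estimated correlation). Glycolysis genes rose in 12 of 20 cases and fell in 2, or 3 adjusted over the list alone, with Eno2 up by 1.03 ± 0.10, Pgk1 by 0.98 ± 0.08 and Ldha by 0.64 ± 0.09, and the lactate transporter Slc16a1 down (-1.13 ± 0.08). For glycolysis the camera adjusted p was 0.03, with an adjusted p = 0.78 with an estimated correlation, and without knockout replicate 1 the camera adjusted p was 0.055. The other 13 lists did not pass. Among them 14 of 26 antioxidant genes fell and 6 rose (camera adjusted p = 0.065), and 5 of 20 NF-kappa-B genes rose and 3 fell, with Icam1 up by 2.54 ± 0.14. Complex I subunits rose in 7 and fell in 10 of 36, and those of complexes II to V rose in 11 and fell in 10 of 41.

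**Figure D2:**
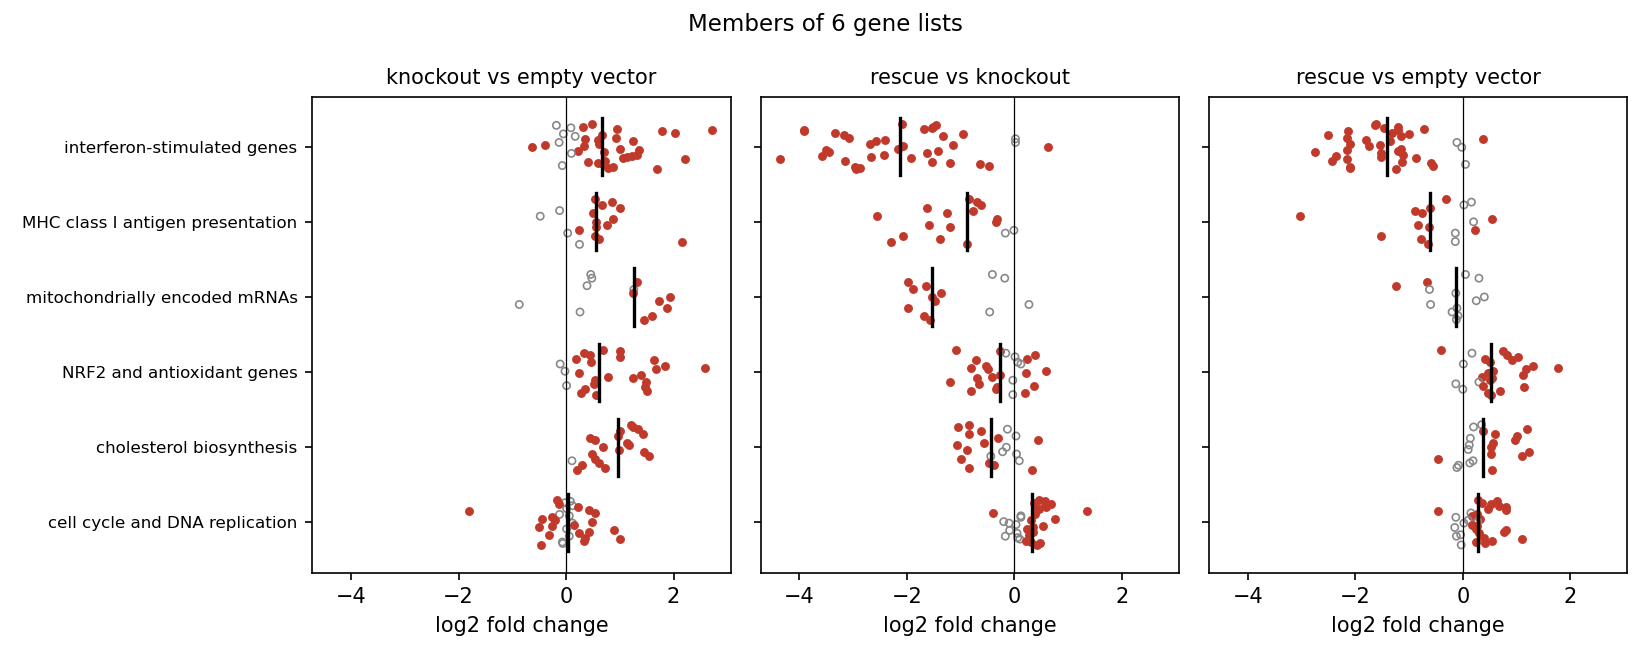
Log2 fold changes (horizontal axis) of the tested members of 6 gene lists in each comparison, with filled points for genes called at an edgeR adjusted p under 0.05, open points for the others and a black line at the list's median. The median of the interferon-stimulated genes lay at 0.68 in knockout against empty vector, -2.13 in rescue against knockout and -1.40 in rescue against empty vector.

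Rescue against empty vector closed the comparison of the 3 lines. With a preset correlation, camera called 9 of 21 lists: interferon-stimulated, antigen-presentation and chemokine genes were lower in rescue, and antioxidant, cell cycle, cholesterol synthesis, glycolysis and both nuclear respiratory-chain lists higher. The estimated correlation left none of the 9, with a smallest adjusted p = 0.38 with an estimated correlation. Hspa1b, a heat-inducible chaperone, was at 8.66 ± 0.556 CPM in empty vector and 52.4 ± 6.32 in rescue (SD, n = 3), and Adgrf5, an adhesion receptor, at 5.84 ± 0.591 and 0.174 ± 0.0729. In all, 2988 genes were higher and 3342 lower in rescue, 47.5% of those tested, and 282 and 439 of them by at least 1 log2 unit. Further increases were largest in Podxl (2.57 ± 0.38), Ly9 (2.22 ± 0.20), Tmem145 (2.09 ± 0.21) and Gsta4 (1.78 ± 0.14), and decreases in the sulfatase Arsg (-4.31 ± 0.19), Ddx60 (-3.52 ± 0.22), Mmp2 (-3.23 ± 0.14) and Sh2d6 (-3.18 ± 0.52). edgeR adjusted p-values of these 10 genes ran from 5.2e-13 for Hspa1b to 0.002 for Sh2d6.

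Interferon-stimulated genes were lower in rescue than in empty vector in 34 of 38 cases and higher in 1, with Irf7 at -2.09 ± 0.08, Usp18, a brake on interferon signalling, at -2.09 ± 0.11, Bst2 at -1.61 ± 0.08 and Irf9 at -1.55 ± 0.08. The median was -1.40 and the camera adjusted p 1.4e-16, with an adjusted p = 0.38 with an estimated correlation. Antigen-presentation genes fell in 10 of 17 cases and rose in 2 (median -0.61), with Tap1 at -1.53 ± 0.07 and H2-D1 at -0.89 ± 0.07, while Pdia3 rose by 0.54 ± 0.09 (camera adjusted p = 0.0083; adjusted p = 0.42 with an estimated correlation). Chemokine and cytokine genes fell in 10 of 20 cases and rose in 4, with Csf1 at -1.35 ± 0.07 and the checkpoint ligand Cd274 at -1.14 ± 0.06 (camera adjusted p = 0.014; adjusted p = 0.38 with an estimated correlation). Mitochondrially encoded mRNAs fell in 2 of 13 cases, or 1 adjusted over the list alone (median -0.12, camera adjusted p = 0.86). Both calls, mt-Co1 and mt-Co2, were lost in some alternatives, with an edgeR adjusted p of up to 0.12. Of the 4 leukocyte markers tested only Cd68 fell (-1.09 ± 0.07).

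Antioxidant genes were higher in rescue than in empty vector in 20 of 26 cases and lower in 1, with Srxn1 up by 1.13 ± 0.07 and Gclm by 0.92 ± 0.07 (median 0.52, camera adjusted p = 1.3e-09; adjusted p = 0.42 with an estimated correlation). Cell cycle genes rose in 22 of 32 cases and fell in 1, or 2 adjusted over the list alone, with Plk1, a mitotic kinase, up by 1.10 ± 0.06 and Mcm4 by 0.81 ± 0.07 (camera adjusted p = 9.7e-07; adjusted p = 0.42 with an estimated correlation). Cholesterol synthesis genes rose in 11 of 21 cases and fell in 1, with Mvd up by 1.23 ± 0.11 and Hmgcs1 by 1.01 ± 0.06 (camera adjusted p = 9.6e-05; adjusted p = 0.63 with an estimated correlation). Glycolysis genes rose in 14 of 20 cases and fell in 3, with Pgam1 up by 0.75 ± 0.08 and Hk1 by 0.70 ± 0.07 (camera adjusted p = 0.0013; adjusted p = 0.63 with an estimated correlation). Complex I subunits rose in 15 of 36 cases and fell in 3, with Ndufb10 up by 0.66 ± 0.08 and Ndufv3 by 0.46 ± 0.08 (median 0.13, camera adjusted p = 0.037; adjusted p = 0.63 with an estimated correlation). Subunits of complexes II to V rose in 14 of 41 cases and fell in 4, with Uqcrfs1 up by 0.72 ± 0.08 and Sdha down (-0.56 ± 0.07; camera adjusted p = 0.023; adjusted p = 0.63 with an estimated correlation). Without empty-vector replicate 2 or rescue replicate 2 these respiratory-chain lists no longer passed, with camera adjusted p-values of up to 0.081 and 0.076. The other 12 lists did not pass, among them hypoxia-inducible factor targets (11 of 23 higher, 4 lower, camera adjusted p = 0.054) and mesenchymal and matrix genes (11 of 23 higher, 4 lower). Except where given, counts adjusted over the list alone differed by at most 1 gene.

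**Figure D3:**
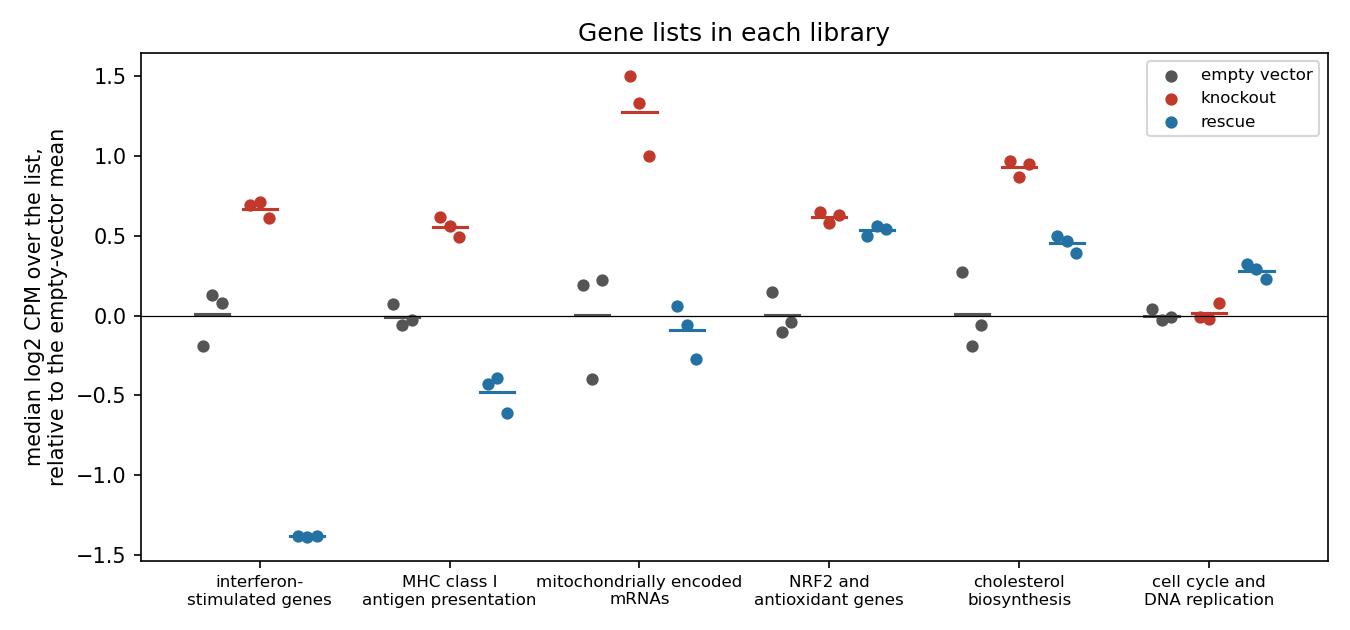
Median log2 CPM over each of 6 gene lists in each library, relative to the empty-vector mean of each gene, with a line at the mean of the 3 libraries of a group. Interferon-stimulated genes lay between 0.61 and 0.71 in the knockout libraries and between -1.39 and -1.38 in the rescue libraries, while antioxidant genes lay between 0.58 and 0.65 in knockout and between 0.50 and 0.56 in rescue.

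Of the 3935 genes that rose in knockout, 2600 (66.1%) fell in rescue against knockout, where independent lists of these sizes would share 1075, and of the 4143 that fell, 2649 (63.9%) rose again, against 1221. Ranked by the smaller of their absolute log2 changes in both comparisons, among genes with at least 5 CPM in the higher group of each comparison, the first 6 down again were Pla2g12a, Prrg1, Itga9, Bco1 (-5.76 ± 0.15), Afp (9.89 to 0.208 CPM) and Olfml3 (-5.50 ± 0.17). By the same rank, the first 6 up again were Gpr161, Myo5b, Traf5, Mum1l1, Ddah1 and Il13ra1 (2.76 ± 0.11). Of the 2600 genes, 697 ended below their empty-vector level at an edgeR adjusted p under 0.05, and of the 2649, 373 ended above it. Both comparisons share the knockout libraries. Simulated unchanged groups gave a mean of 0.12 reversed genes over 50 simulations against 5249 observed. Unchanged groups give few calls in either comparison, so this low count follows from the setting. It does not show how many genes would count as reversed if each line differed on its own from the others. The covariance of the log2 changes across genes was -0.551 against -0.0189 simulated, with a correlation of -0.77 against -0.528. Part of the excess over independent lists may come from the shared libraries, which are too few to split.

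Of the genes that rose in knockout, 1607 (40.8%) were also higher in rescue than in empty vector, against 882 for independent lists, and of those that fell, 1825 (44.1%) were also lower, against 1039. A gene partly restored in rescue can be counted both as reversed and as kept, so the shares are not alternatives. Gsta4, for instance, fell from knockout to rescue (-0.81) but stayed above empty vector (1.78). If the knockout and empty-vector labels were exchanged, which the Ndufa4l2 counts do not settle, reversed and kept shares would change places. By the same rule, the first 6 kept increases were in Hspa1b, Gsta4, Gsta3, a glutathione transferase (11.3 ± 2.30, 79.4 ± 3.64 and 33.6 ± 1.90 CPM in empty vector, knockout and rescue), Hspa8, a constitutive chaperone (428 ± 59.8, 1400 ± 69.4 and 1420 ± 152 CPM), Tmem145 (1.94 ± 0.790, 8.11 ± 0.843 and 8.11 ± 0.385 CPM) and Sim2 (1.90 ± 0.560, 8.80 ± 1.21 and 5.64 ± 0.889 CPM). Gsta genes share reads between near-identical copies and are uncertain. The first 6 kept decreases were in Ppp1r15a (-2.29 ± 0.19 in rescue against empty vector), Il23a (-2.13 ± 0.18), Sh2d6, Ccdc137 (-1.70 ± 0.09), Ubap1l (-1.68 ± 0.18) and Angptl4, a lipase inhibitor (-2.34 ± 0.08). These comparisons share the empty-vector libraries: simulated unchanged groups gave a mean of 0.06 kept genes against 3432 observed, and a covariance of 0.0167 against 0.133. The low simulated count again follows from groups without a difference. It does not show how many genes would count as kept if each line differed on its own. The correlation of the log2 changes across genes went the other way, at 0.28 against 0.483 simulated. Part of the excess over independent lists may come from the shared libraries. Without knockout replicate 3 the fall of Sh2d6 in knockout did not pass (edgeR adjusted p = 0.05).

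The authors' deposited table gave 3586 genes higher and 3528 lower in knockout against empty vector at its adjusted p under 0.05, 3543 and 3718 in rescue against knockout, and 2597 and 2689 in rescue against empty vector. Of the 8078, 7567 and 6330 genes called in the tests above, 6843, 6841 and 5207 were also called in that table, all in the same direction. Both rest on the same libraries, so this is not independent support.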

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

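Which direction held more calls depended on the processing. In knockout against empty vector 3935 rose and 4143 fell, but 4142 and 3868 with RLE factors and 3929 and 3681 with DESeq2. In rescue against knockout 3928 rose and 3639 fell, but 3698 and 3805 with RLE factors, 3480 and 3644 with DESeq2 and 3866 and 4047 with only the groups compared in the fit. In rescue against empty vector 2988 rose and 3342 fell, but 3288 and 3100 with upper-quartile factors, 3068 and 2953 with only the groups compared and 3256 and 2963 with library totals only. Without 1 library, 3587 to 4209 genes rose and 3774 to 4217 fell in knockout against empty vector, and Ndufa4l2 changed by 2.19 to 2.89 in rescue against knockout and by -0.68 to 0.01 in knockout against empty vector. With a log2 change of at least 1 required, the counts up and down were 1083 and 523 in knockout against empty vector, 276 and 1120 in rescue against knockout, and 282 and 439 in rescue against empty vector, with 678 and 155 genes reversed and 160 and 118 kept, since most calls are small. Scaling by library totals only was an alternative chosen after seeing the data. With it, 5916 genes rose in rescue against knockout and 4241 that fell in knockout rose again. This scaling moves the median of all genes by 0.18 in rescue against knockout. There 3 named genes changed sign, Atp5g3 to 0.14 (from -0.05), Ndufa4 to 0.01 (from -0.17) and Rela to 0.01 (from -0.17). Ndufa4 and Rela no longer passed under it (edgeR adjusted p = 0.89 and 0.88), so their calls were lost and not reversed. With an estimated correlation camera called 0, 0 and 0 lists in the 3 comparisons instead of 7, 8 and 9; fry, which tests a list without reference to other genes, called 14, 16 and 13. Of 24 list calls, 21 held under all other settings in which they were tested. The list of mitochondrially encoded mRNAs could not be tested with the mitochondrial genome left out. Of 461 calls of named genes, 422 held under each of the 18 settings in which they were tested. Of 546 results for named genes, called or not, 528 were tested with the mitochondrial genome left out and 538 with only the groups compared in the fit. The replicate block gave 3852 and 4038 genes in knockout against empty vector; libraries sharing a number correlated at -0.15 to 0.05 after group means were removed, so the numbers do not pair them. Depth limits Ndufa4l2, with 6 to 16 counts in the empty-vector libraries.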

Other observations

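The tests in this part were chosen only after the results were seen, except those on GC content and on regrouped libraries. Lysosomal genes followed the leukocyte marker Cd68, itself a lysosomal protein. Of 34 tested, 30 rose and none fell in knockout against empty vector (median 0.66, camera adjusted p = 5.6e-12; adjusted p = 0.23 with an estimated correlation), and 32 fell and 1 rose in rescue against knockout (median -1.09, camera adjusted p = 9.3e-18; adjusted p = 0.12 with an estimated correlation). In rescue against empty vector 21 were lower and 3 higher (median -0.29, camera adjusted p = 2.1e-05; adjusted p = 0.30 with an estimated correlation). Lamp1, a lysosomal membrane protein, stood at 443, 985 and 514 CPM in empty vector, knockout and rescue, and the protease Ctsd at 1000, 1760 and 815.

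Cytosolic chaperones rose in 20 of 26 cases in rescue against empty vector and none fell (median 0.54, camera adjusted p = 6.6e-11; adjusted p = 0.12 with an estimated correlation), and in 21 cases against knockout, with 2 lower (median 0.49, camera adjusted p = 5.6e-07; adjusted p = 0.14 with an estimated correlation). In knockout against empty vector 12 rose and 12 fell (camera adjusted p = 0.49). Hsp90aa1 stood at 1270, 1860 and 2980 CPM and Dnajb1 at 43.7, 73.8 and 94 CPM in empty vector, knockout and rescue. Of 279 families of genes sharing the start of their symbol, the Slc family of membrane transporters had the smallest camera adjusted p in knockout against empty vector and in rescue against knockout. Of 212 Slc genes, 117 rose and 40 fell in the former (median 0.41, camera adjusted p = 0.00072; adjusted p = 0.84 with an estimated correlation), and 25 rose and 138 fell in the latter (median -0.54, camera adjusted p = 2e-10; adjusted p = 0.65 with an estimated correlation). In rescue against empty vector 27 were higher and 99 lower (median -0.23, camera adjusted p = 0.011, and adjusted p = 0.83 with an estimated correlation). Silent genes also switched: 31 genes with at most 0.5 CPM in every empty-vector library and more than 2 CPM in every knockout library included Afp, Itga9, Gli2 and Postn, and 26 of them were again at or under 0.5 CPM in every rescue library. The reverse held for 6 genes, Eprn, Islr2, Ldb2, Myo5b, Xlr3a and Zfp618, of which 4 were above 2 CPM in every rescue library.

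Neighbouring genes shifted together in knockout against empty vector and mostly less in rescue against empty vector: of 147 windows of up to 60 genes, the window at 105.7 to 126.8 Mb of chromosome 3 had a median of 0.43 in knockout against empty vector and -0.04 in rescue against empty vector, and chromosome 16 as a whole had 0.24 and -0.05 (300 genes). Among losses, 3.4 to 34.5 Mb of chromosome 18 had -0.32 and -0.08, while 3.3 to 30.5 Mb of chromosome 13 (-0.32 and -0.18) and 4.8 to 36.7 Mb of chromosome 1 (-0.18 and -0.20) kept more in rescue. The spread of window medians in knockout against empty vector was 0.135, above the 0.0886 that was the most among 1000 shuffles of gene positions, and 0.117 against 0.0805 after a trend on GC content and length was removed, while in rescue against empty vector it was 0.0617 against 0.0663, so in knockout neither chance placement nor that trend accounts for it. A dosage change of the knockout line would be inherited by rescue cells. Over all windows, however, only 0.12 of the shift was kept there (slope, 95% bootstrap interval 0.047 to 0.20), although the shared empty-vector libraries push this slope up. Windows were resampled as independent, though those of a chromosome, such as chromosome 16, could shift alike, so the interval may be too narrow. The pattern may reflect rescue cells that do not descend from the sequenced knockout clone, or a reversible regulation of regions, and neither was tested; exchanged labels of knockout and empty vector stay open, as Ndufa4l2 differed by -0.36 (edgeR adjusted p = 0.47), and by -0.68 to 0.01 with 1 library left out.

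Interferon-stimulated genes were highest in knockout, lower in empty vector and lowest in rescue. To look for leukocytes among the knockout cells, 8 leukocyte transcripts were examined. Their median gain was 0 CPM, with at most 2 counts in any library, against 129 CPM for Cd68. The 8 were chosen afterwards as having almost no counts in the line, so their low gain was fixed by that choice. All 4 leukocyte markers with enough counts rose in knockout, Lyz2 among them from 0.949 to 7.49 CPM. Cells carrying the 8 transcripts were not seen, but other leukocytes are not excluded. Mitochondrial RNA might trigger an interferon response. In rescue against empty vector, mitochondrially encoded mRNAs had a median of -0.12 and interferon-stimulated genes -1.40, so the levels did not fall in step. All 13 mitochondrially encoded mRNAs lay above the interferon median, though mt-Co1 (-0.66) and mt-Co2 (-1.25) were called lower and 11 were not called. The call of mt-Co1 was lost in 2 alternatives and that of mt-Co2 in 8, with an edgeR adjusted p of up to 0.12. Where in the cell this RNA lay was not measured, so a part for it stays open, there and for the rise in knockout (1.26 and 0.68). After a trend on GC content and length was removed, the median in rescue against knockout was -2.20 instead of -2.13. Effects of the lentivirus, of puromycin or of clone choice were not tested.

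With 3 libraries per group there are 10 splits of the 6 libraries of a comparison, too few for a share under 0.05. The real grouping was the only 1 of 10 with as many genes called by edgeR in each comparison, at 8078, 7567 and 6330 genes, where the highest other split called 0, 0 and 0 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 in edgeR the real groupings gave 8543, 8127 and 7127 genes and the highest other splits 505, 231 and 998. Every other split mixes libraries of both groups, so the group difference widens its spread. Few calls there follow from the design and do not measure how many calls unchanged groups would give.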
